A study of Mus musculus with 6 samples.

How the data were processed

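RNA abundance was measured in 6 samples of mouse ovarian cancer cells, 3 of the parental line ID8 and 3 of ID8-M, a line grown from cells that parental ID8 had given rise to in the peritoneal cavity of mice. Per the labels, total RNA was turned into biotinylated cRNA with a kit made for Illumina arrays. All 6 samples lay on 1 bead chip, with the parental samples at positions A to C and the ID8-M samples at positions D to F. Chip position and cell line therefore cannot be told apart.

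The deposited scanner table gives, per probe and array, the mean bead intensity on a linear scale, the number of beads, the standard error over beads and a detection p-value. Per the file headers and the values, the deposited intensity was neither background subtracted nor normalized. The detection p-value moved in steps that correspond to 936 negative control probes, and per the file headers it is given for each probe on each array. A second deposited table holds normalized intensities. Set against the scanner table, each of its columns kept the order of its own array with a rank correlation of 1, and its values followed plain quantile normalization without background subtraction, with a largest gap between 0.109% and 1.65% per array. Its values are on the linear scale, with medians between 143.36 and 143.41. The scanner software is not given in the sources used here.

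Intensities were background corrected, quantile normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values, with an offset of 16. The mean background estimated per array lay between 128.9 and 138.9 intensity units. Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. A RefSeq gene of the GRCm38.p6 assembly was matched for 34807 probes, and 0 symbols had to be updated. No gene was named from a probe with several symbols. Probes with a detection p under 0.05 on all 3 arrays of at least 1 line were tested, which left 16221 probes and 8933 genes. A gene was represented by its tested probe with the highest mean over all 6 arrays, and 3413 genes had more than 1 tested probe.

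Each probe was fitted with limma (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the tested probes. A probe or gene with an adjusted p under 0.05 is called changed. The residual degrees of freedom were 4 before moderation. Errors given with fold changes are standard errors from this fit. A probe not detected on any array of a line has only a bound there, and so has, for the genes named, a probe detected on 1 array of a line with a mean there below the mean of the lowest detected signals, a case added after the values were seen. Such differences are given as "at least N-fold", which sets the mean of the brighter line against the dimmer line's mean of, per array, the lowest normalized signal among detected probes or the probe's own signal if that was higher. These bounds hold for the background-corrected scale.

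Before the data were examined, 33 gene lists were fixed, 25 of programmes and 8 of markers of other cell types or of cell stress. The 26 lists with at least 5 tested genes were compared with all other genes by camera, from limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists. An estimated correlation and fry were run beside it. The fry test asks whether the genes of a list moved, without setting them against other genes. Also fixed beforehand was the rule for the genes to name. It takes the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between lines, without clone-type names. It adds up to 2 called rises and 2 called falls per list, or the member with the smallest adjusted p where none was called, and always Ccl2, Csf1, Cx3cl1, Cxcl12, Il6, Vegfa, Tgfb1, Spp1, Cdh1, Vim, Cd44 and Trp53. Spp1 and Trp53 were not analysed here, since no probe carries either symbol in the annotation used.

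The procedure was tested on simulated data for the comparison of 3 ID8-M with 3 parental arrays. Among 16838 tested simulated probes, 14.6% of those changed by 0.5 on the log2 scale were recovered, 70% of those changed by 1, 82% by 2 and 98% by 3. The simulation changed 48 tested probes by 0.5 and 50 by each larger size, against 4610 probes called in the data. Its adjusted threshold was therefore stricter than in the data. It also added background noise to a spread between arrays that already held it. These shares therefore do not carry over to the data. Of 150 calls, 18 fell on unchanged probes, which is 12% and lies above the 5% that the threshold aims at. The simulation of lists ran on 9191 genes, called 0 of 27 lists when none was moved and 3 when 1 list was moved by 0.3. The moved list was among those 3, and the other 2 had not been moved as lists. With the individually changed probes left out, a form added after the first result was seen, 9121 genes remained and only the moved list was called.

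Alternatives concerned the background correction, the scaling between arrays, the deposited normalized table, the filter on dim probes (none, or a detection p under 0.01 on all 6 arrays), the variance model, array weights, the replicate number as a block, the probe that stands for a gene, the correlation between genes, and each array left out in turn. One alternative, the removal of each chromosome's median difference, was added after the data were seen. The RefSeq table served to tell which genes share a chromosome and in which order. The labels name no genome build, so no positions of that assembly are given.

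The median number of beads per probe was 37 to 39 per array, and the median standard error over beads was 3.78% to 4.18% of the intensity of tested probes. The number of arrays, 3 per line, limits the precision. The labels do not say whether the samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No table of one array was a copy of another, with at most 2 probes of equal value between a pair of arrays.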

Results

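Gene expression was compared between ID8, a mouse ovarian epithelial cancer cell line, and ID8-M, a line derived from it in vivo. Per the labels, parental ID8 cells were injected into the peritoneal cavity of 8-week-old mice, and cells from the ascites were taken 12 weeks later, cloned and passaged. Both lines were grown in the same medium with 4% serum, and 3 samples of each were hybridised to bead arrays. The series title names faster peritoneal spread, macrophage recruitment and M2 polarization, an alternative form of macrophage activation, as the questions behind the comparison. Between 16386 and 17186 probes were detected per array. Over the tested probes, arrays of the same line correlated at 0.9933 to 0.9946, and arrays of different lines at 0.9673 to 0.9704.

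The cells of ID8-M differed from parental ID8 in the abundance of 2748 of 8933 tested genes, 1378 higher and 1370 lower. Large differences were mostly rises, since 360 genes were at least 2-fold higher and 113 at least 2-fold lower. At 4-fold, 96 genes were higher and 18 lower. Per probe, 4610 of 16221 passed (limma, Benjamini-Hochberg adjusted p under 0.05), 2203 higher and 2407 lower, of which 516 rose and 168 fell at least 2-fold. Which direction held the majority depended on the setting, with 2551 probes higher and 1935 lower with cyclic loess. A further view is detection alone: 190 genes were detected on all 3 ID8-M arrays and on no parental array, and 62 the other way round, of which 183 and 59 were called. The count of 2-fold probes depended on the background setting, with 207 probes at 2-fold without background correction, and it was 312 (214 higher and 98 lower) among probes with a detection p under 0.01 on all 6 arrays, a filter that leaves out probes detected in only 1 line. Of 115 called genes picked by the naming rule, 38 had under 50% of their log2 difference without background correction. Beside genes given as bounds these were, among the genes below, the rises Traf1 (0.76), Tap2 (0.62), Il33 (0.50), Kit (0.45) and Mpeg1 (0.37). The falls among them were Ifit3 (−0.16), Plvap (−0.20), Cxcl10 (−0.21), Mmp2 (−0.33), Cox7b (−0.35) and Ripply1 (−1.15).

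The largest rises included secreted, epithelial and metabolic genes. Wfdc1, a secreted protein with a whey acidic protein domain, was at least 32.7-fold higher in ID8-M (limma adjusted p = 2.04e-08). Cxcl1, a chemokine that attracts neutrophils, was at least 23-fold higher (limma adjusted p = 2.39e-08). Gstk1, a glutathione S-transferase, was at least 19-fold higher, Papss2, which makes the sulfate donor for sulfation, at least 13.4-fold, Map7, a microtubule-associated protein, at least 11.1-fold, and Extl1, an exostosin-like glycosyltransferase, at least 9.7-fold. None of these 6 genes was detected on any parental array. Dmkn, a secreted protein of the epidermis, rose by 5.62 ± 0.09 (SE, log2), from 7.33 to 12.96. Slc39a4, a zinc importer, rose by 4.97 ± 0.13, Krt14, a basal keratin, by 4.48 ± 0.08 and Klhl6 by 4.07 ± 0.14. Their parental means of 5.52, 5.55 and 5.48 lay near the mean of the lowest detected signals, 5.41. Slc39a4 and Klhl6 were detected on only 2 parental arrays. Without background correction their differences were 3.12 and 2.30, and that of Krt14 was as low as 2.70 among the alternatives. These values and bounds are those of each gene's brightest probe. Dimmer probes, also undetected in parental ID8, gave lower bounds, at least 13.5-fold and 7.51-fold for Wfdc1, 12.2-fold for Gstk1, 6.05-fold for Extl1, 2.12-fold for Papss2, 2.45-fold for Map7, 1.35-fold for Slc39a4 and 1.25-fold for 1 of 2 others of Dmkn. Each of these 10 genes was higher on all 3 ID8-M arrays than on all 3 parental arrays, as the rule for naming them required.

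Among the largest falls, Gpnmb, a transmembrane glycoprotein, was at least 8.13-fold lower in ID8-M, Slitrk5, a neuronal transmembrane protein, at least 6.31-fold, Tmem108 at least 5.76-fold, Cldn2, a tight junction claudin, at least 4.06-fold, and Sprr2k, a small proline-rich protein, at least 3.12-fold. These 5 genes were not detected on any ID8-M array, and near-identical members of the Sprr2 family may share signal with Sprr2k. Vat1l was at least 9.44-fold lower and Thbs1, a matrix glycoprotein that restrains angiogenesis, at least 4.66-fold, each detected on 1 ID8-M array with a mean at background there (log2 differences of −1.67 and −0.99 without background correction). The log2 difference was −3.34 ± 0.11 for Peg3, an imprinted zinc finger gene, −2.42 ± 0.09 for Ripply1 and −2.35 ± 0.10 for Ncam1, a cell adhesion molecule. Another tested probe of Ncam1 fell by less (−0.70), and another of Peg3, undetected in ID8-M, was at least 2.36-fold lower. The largest limma adjusted p among these 10 falls was 1.01e-05, that of Thbs1.

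**Figure D1:**
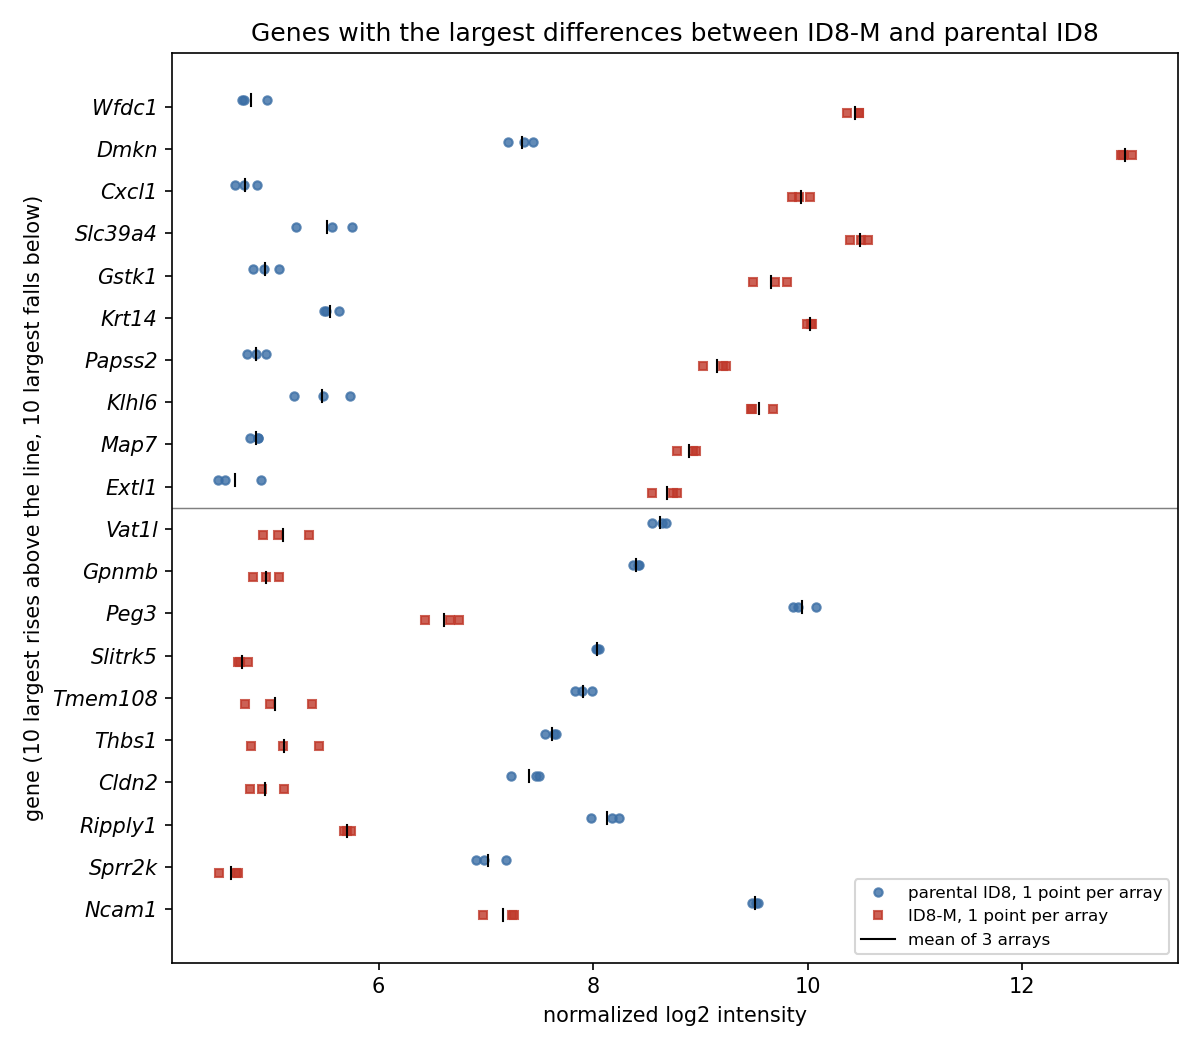
Normalized log2 intensity (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per array and a bar at the mean of 3 arrays for each line. The arrays of the 2 lines do not overlap for any of the genes, as the rule for choosing them required. Points of a line in which a gene was not detected, and those of Vat1l and Thbs1 in ID8-M, lie at background and show no level.

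More epithelial genes rose than fell in ID8-M, and more mesenchymal genes fell than rose. Of 19 tested epithelial adhesion and keratin genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 difference of 0.68. Besides Krt14, Itgb4, an integrin subunit of hemidesmosomes, rose by 3.21 ± 0.10. Cdh1, which encodes E-cadherin, was the exception and fell by 0.61 ± 0.11 by its brightest probe (limma adjusted p = 0.00468). Its other tested probe, detected on only 2 ID8-M arrays, was not called (limma adjusted p = 0.465). Of 22 tested mesenchymal and epithelial-mesenchymal transition genes, 13 fell and 2 rose (14 and 3 adjusted over the list alone). Acta2, smooth muscle actin, fell by 2.17 ± 0.09, and Twist2, a transcription factor of mesenchymal cells, was at least 2.76-fold lower. Tpm2, a tropomyosin, was at least 6.22-fold higher and Col6a1, a collagen VI chain, rose by 1.20 ± 0.10. Vim, the mesenchymal intermediate filament vimentin, differed by −0.11 ± 0.08 and was not called (limma adjusted p = 0.331). Of 21 tested TGF-beta and YAP target genes, 10 fell and 2 rose (11 and 4 adjusted over the list alone). Ankrd1, a target of YAP, fell by 2.15 ± 0.08 and Tgfb2, a TGF-beta ligand, fell by 1.39 ± 0.09, while Tgfb1, another ligand, rose by 0.77 ± 0.15.

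Against all other genes, the epithelial list was shifted up (camera adjusted p = 5.58e-06), the mesenchymal list down (0.00474) and the TGF-beta and YAP list down (0.0267). Each of these 3 calls was lost when camera estimated the correlation between genes. The camera adjusted p was then 0.201 for the epithelial list, 0.201 for the mesenchymal list and 0.226 for the TGF-beta and YAP list. The estimated correlation was 0.0314 for the epithelial list, −0.0398 for the mesenchymal list and −0.0127 for the TGF-beta and YAP list. The last 2 values lie below the preset 0.01, so a higher correlation between genes is not what ended those calls. What ended the call of the epithelial list was not tested. Krt7, Krt8, Krt18 and Myc lie on 1 chromosome (GRCm38.p6 annotation), whose 380 tested genes had a median log2 difference of 0.36, and Cdh1 lies on another, whose 491 tested genes had a median of −0.31. With the chromosome's median difference removed, the Cdh1 difference was −0.30 and was no longer called (limma adjusted p = 0.0871). All 3 list calls were kept when each chromosome's median difference was removed.

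**Figure D2:**
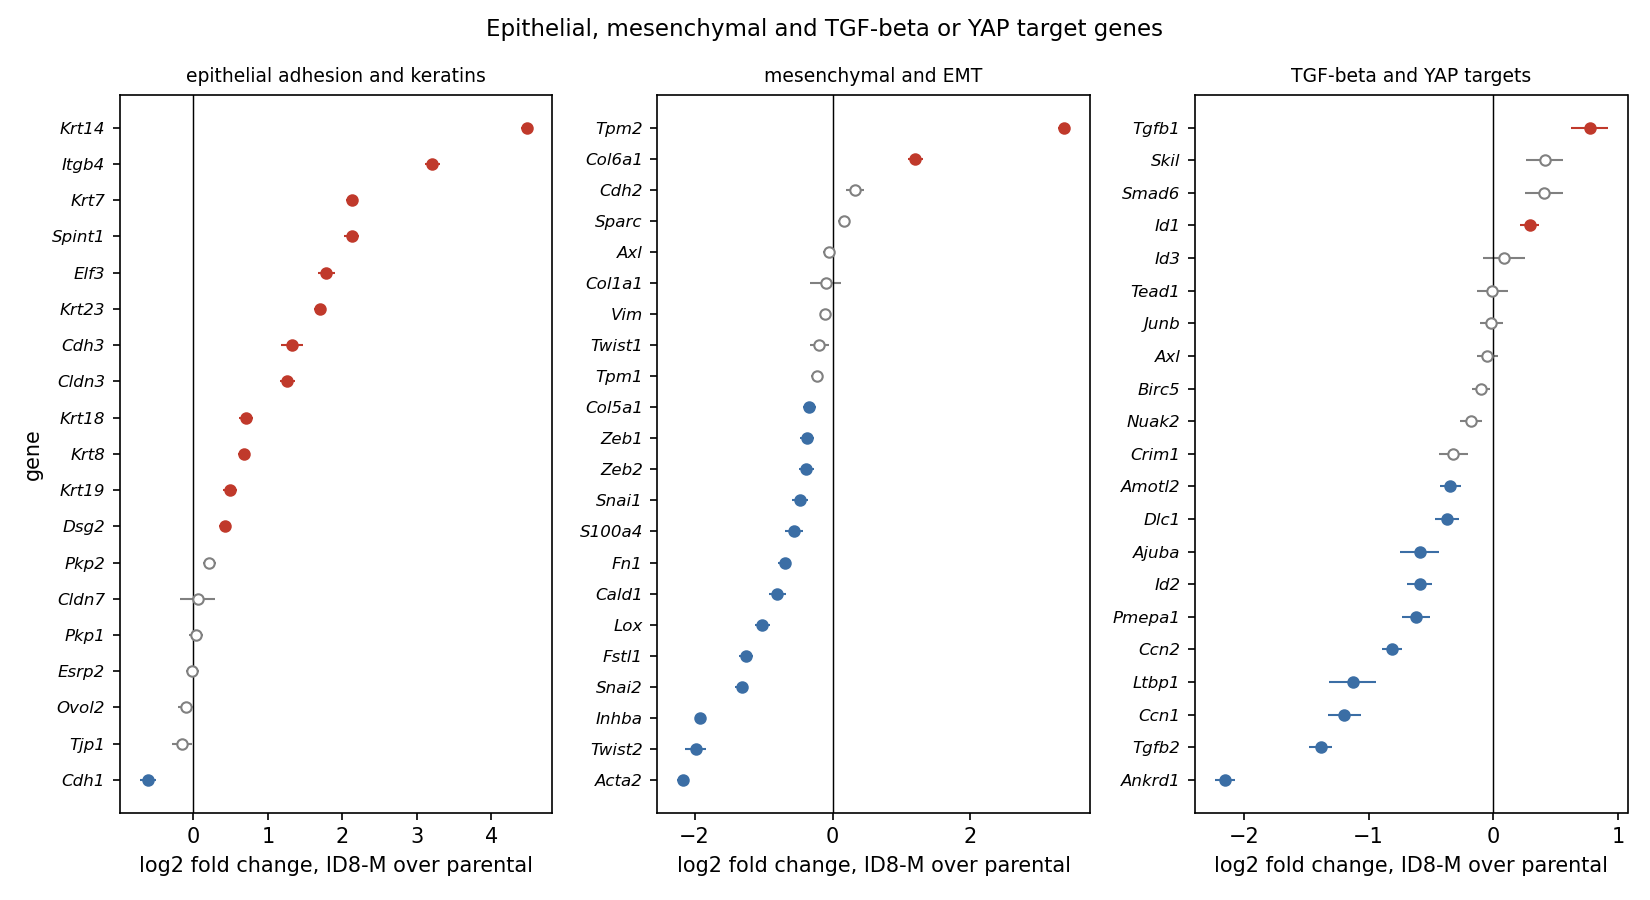
Log2 fold change of ID8-M over parental ID8 (horizontal axis) for each tested gene of 3 fixed lists, with bars for the standard error from 3 arrays per line. Filled red points were called higher, filled blue points lower, and open points were not called. Of the epithelial genes 12 lie in red, and of the mesenchymal genes 13 lie in blue. Krt23, Elf3, Tpm2, Twist2 and Cdh2 lay at background in 1 line and are drawn at their fitted values, so that their distance is not a measured fold.

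Factors that attract or feed macrophages moved both ways. Of 13 tested monocyte and macrophage chemoattractants and growth factors, 4 rose and 4 fell (5 and 4 adjusted over the list alone), and the list was not shifted against other genes (camera adjusted p = 0.934). Without other genes as the reference, the list passed (fry adjusted p = 0.0382). Csf2, the granulocyte-macrophage colony stimulating factor, was at least 2.24-fold higher, against a parental mean at background (log2 difference of 0.43 without background correction). Vegfa, an angiogenic factor, rose by 0.73 ± 0.12 and Cx3cl1, the chemokine fractalkine, by 0.71 ± 0.09. Csf1, the main growth factor of macrophages, fell by 1.77 ± 0.13 and Cxcl12, a chemokine that guides many leukocytes, fell by 1.42 ± 0.10. Ccl2, the classic monocyte chemoattractant, differed by 0.08 ± 0.10 and was not called (limma adjusted p = 0.617). Among 17 tested secreted factors that favour alternative macrophage activation, 3 rose and 3 fell (4 and 4 adjusted over the list alone), again without a shift of the list (camera adjusted p = 0.886, fry adjusted p = 0.762). Nt5e, the ecto-enzyme that makes adenosine, rose by 1.87 ± 0.13 (at least 1.4-fold by its other tested probe, undetected in parental ID8) and Il33, an alarmin cytokine, by 1.12 ± 0.11. Il6, a cytokine of inflammation, was not detected on any array. Of 4 tested members of the list of neutrophil and interferon-induced CXC chemokines, which leaves out Cxcl12, 3 rose and 1 fell (3 and 1 adjusted over the list alone), too few for a list test. Besides Cxcl1, Cxcl17 rose by 1.31 ± 0.13, whereas Cxcl10, an interferon-induced chemokine, fell by 0.55 ± 0.14. Leaving out any 1 of 4 arrays (parental 1, parental 3, ID8-M 1 or ID8-M 3) ended the Cxcl10 call, with adjusted p up to 0.0753.

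**Figure D3:**
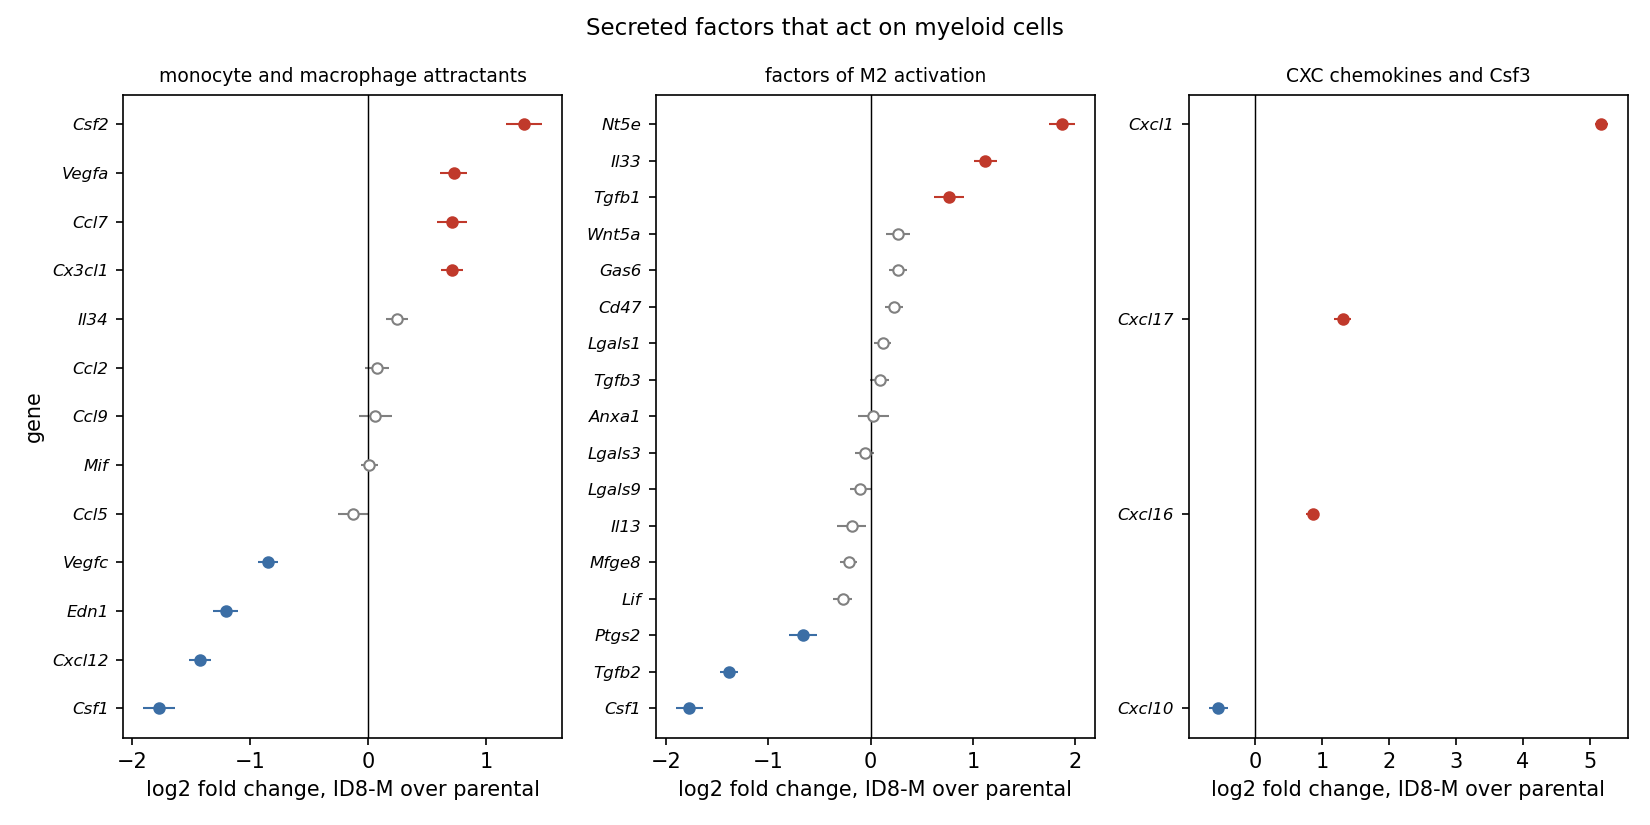
Log2 fold change of ID8-M over parental ID8 (horizontal axis) for each tested gene of 3 fixed lists of secreted factors, with bars for the standard error from 3 arrays per line. Filled red points were called higher, filled blue points lower, and open points were not called. Cxcl1, Csf2 and Ptgs2 are drawn at their fitted values although they lay at background in 1 line, so that their distance is not a measured fold.

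Immune response genes rose more often than they fell, but none of these lists was shifted against other genes. Without other genes as the reference each list passed, with a fry adjusted p of 7.65e-05 for NF-kappaB targets and 0.000893 for the interferon list. The MHC class I list gave a fry adjusted p of 0.000445 and the checkpoint list 0.00247. Of 18 tested NF-kappaB targets 7 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.253). Traf1, a signalling adaptor, rose by 1.67 ± 0.15, and Saa3, an acute phase protein, was at least 2.53-fold lower, against an ID8-M mean at background (log2 difference of −0.47 without background correction). In the type I interferon list, 8 of 22 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0963), with Ifi47, an interferon-induced GTPase, up by 2.78 ± 0.14 and Oasl1 up by 1.86 ± 0.08 (1.48 by another tested probe, and at least 1.27-fold by 1 more, undetected in parental ID8). The 2 falls of that list were Ifit3 (−0.44 ± 0.12) and Irf9 (−0.32 ± 0.10, not called by its other tested probe). Leaving out any 1 of 4 arrays ended the Ifit3 call, and leaving out any 1 array ended the Irf9 call. For antigen presentation on MHC class I, 7 of 16 rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0963). Psmb8, an immunoproteasome subunit, rose by 2.31 ± 0.17 (at least 1.47-fold by its other tested probe, undetected in parental ID8) and Tap2, a peptide transporter, by 1.28 ± 0.21, while H2-M3, a class Ib molecule, fell by 0.49 ± 0.09. Of 10 tested checkpoint genes and ligands of NK or T cells, 3 rose and none fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.294), with Cd276, a B7 family member, up by 1.19 ± 0.10 and Cd59a, a complement inhibitor, up by 0.84 ± 0.09.

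Matrix and adhesion genes changed in both directions. Among 20 extracellular proteases and inhibitors 5 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.294), and the collagenase Mmp13 rose by 0.77 ± 0.09 while the gelatinase Mmp2 fell by 0.91 ± 0.15. Among 25 integrins and matrix receptors 5 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.294). Itga11, a collagen-binding integrin subunit, rose by 2.76 ± 0.09, and Itgb1, the common beta subunit, fell by 0.75 ± 0.12. Cd44, a hyaluronan receptor, fell by 0.34 ± 0.09 by its brightest probe, but 2 of its other probes were called higher, so its direction is uncertain. Leaving out any 1 of 5 arrays also ended the call of that probe, with adjusted p up to 0.0755, and only leaving out ID8-M 2 kept it. Of 19 collagen and basement membrane genes 3 rose and 7 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.314). Fbln1, fibulin 1, was at least 3.39-fold higher by its brightest probe, while its 2 other tested probes, also undetected in parental ID8, gave bounds of 1.42-fold and 1.34-fold, and Lama1, a laminin chain, was at least 2.52-fold lower.

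Genes of hypoxia and glycolysis were shifted up under the preset correlation between genes. Of 31 tested, 8 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0286), with Ndrg1 up by 1.26 ± 0.18 and P4ha2, a collagen prolyl hydroxylase, up by 1.24 ± 0.09. With an estimated correlation, which was 0.246 for this list against the preset 0.01, the camera adjusted p was 0.512. The call was also lost without parental 2 (camera adjusted p = 0.06) or without ID8-M 1 (0.0959). Cholesterol genes included 4 rises and 1 fall among 17 (4 and 1 adjusted over the list alone, camera adjusted p = 0.655), with Cyp51, a sterol demethylase, up by 0.77 ± 0.10. For fatty acid metabolism, 2 of 27 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.68), and Acacb, an acetyl-CoA carboxylase, was at least 2.1-fold higher, against a parental mean at background (log2 difference of 0.40 without background correction), while Fabp5, a fatty acid carrier, fell by 1.99 ± 0.20. In the NRF2 and oxidative stress list, 5 of 26 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.528). Gstm2 rose by 2.38 ± 0.08 and Gsta3 by 1.32 ± 0.10, and Gsta2 fell by 1.07 ± 0.11, but Gsta1 and Gsta2 are near-identical and their probes may share signal. Of 38 oxidative phosphorylation genes 3 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.756), and Cox7b fell by 0.73 ± 0.14. That call was lost with the chromosome's median difference removed (limma adjusted p = 0.0607 for Cox7b). The rises of Ndufb9 and Cox6c and the fall of Ndufa1 were lost in the same way (limma adjusted p = 0.45, 0.918 and 0.801). Leaving out any 1 of 5 arrays also ended the Cox6c call.

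Genes of growth and stress programmes changed in both directions, and none of these lists that were tested was shifted against other genes. Among 47 cell cycle and mitosis genes 2 rose and 7 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.164), and Ccnd1, cyclin D1, rose by 0.63 ± 0.08 while Mybl2 fell by 0.69 ± 0.08. Of 22 p53 targets 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.528), with Cdkn1a, a cell cycle inhibitor, up by 0.82 ± 0.10. Growth factor receptors and ligands gave 9 rises and 8 falls among 27 (11 and 9 adjusted over the list alone, camera adjusted p = 0.774). Kit, a receptor tyrosine kinase, rose by 1.07 ± 0.17 and Igf1 fell by 1.36 ± 0.11. Of 11 Wnt and Notch targets 5 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.291), and Nrarp, a Notch target, rose by 3.84 ± 0.17 while Sp5, a Wnt target, fell by 1.43 ± 0.12. Stem and progenitor markers gave 6 rises and 3 falls among 12 (6 and 3 adjusted over the list alone, camera adjusted p = 0.164). Ly6e rose by 2.94 ± 0.08 and Abcb1b, a drug efflux pump, by 1.88 ± 0.10, while Nes, nestin, fell by 0.95 ± 0.13, although its other tested probe was not called (limma adjusted p = 0.0863). In the unfolded protein and integrated stress list 7 of 28 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.329), with Vldlr up by 1.54 ± 0.11 and Ddit3, a stress transcription factor, up by 0.93 ± 0.14. Of 4 tested imprinted and X-inactivation transcripts only Peg3 was called, a fall (2 falls adjusted over the list alone). The median and the list test differed in sign for the chemoattractant, p53 and cholesterol lists and for the immediate early list.

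Markers of other cell types were mostly not detected. Of 23 macrophage markers on the array 2 were tested, of which Mpeg1, a pore-forming protein of macrophages, rose by 0.97 ± 0.15 and Cd14 fell by 0.35 ± 0.09 (1 and 1 adjusted over the list alone). The Cd14 call ended without parental 1, parental 3 or ID8-M 3, with adjusted p up to 0.0767, and with the chromosome's median difference removed (log2 difference −0.16 for Cd14, limma adjusted p = 0.249). Of 16 lymphocyte markers on the array 2 were tested and neither was called (0 adjusted over the list alone), with a difference of 0.12 ± 0.07 for Cd8b1 (limma adjusted p = 0.264). Of 15 neutrophil markers on the array 0 were tested, and of 9 erythroid markers only Tfrc, which differed by −0.11 ± 0.11 and was not called. Among 3 tested fibroblast markers Fbln1 rose and Dcn, decorin, rose by 0.61 ± 0.08 (2 rises and 1 fall adjusted over the list alone). Of 12 immediate early and heat shock genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.528), and Fos was at least 2.15-fold higher, against a parental mean at background (log2 difference of 0.41 without background correction), while Dusp1, a phosphatase, fell by 0.87 ± 0.08.

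Alongside the epithelial genes, mesothelial and ovarian surface epithelium markers were shifted up in ID8-M, 7 of 16 rising and 1 falling (8 and 1 adjusted over the list alone, camera adjusted p = 0.0073, adjusted p = 0.201 with an estimated correlation). The rises include Krt8 (0.68), Krt18 (0.70) and Krt19 (0.50), which belong to the epithelial list as well, so the shifts of these lists are not separate results. Krt8 and Krt18 also lie on the chromosome with a median log2 difference of 0.36. The call of the mesothelial list was kept when each chromosome's median difference was removed. Bnc1, a transcription factor, rose by 1.74 ± 0.11 and Upk3b, a uroplakin, by 1.41 ± 0.09, while Aldh1a1, a retinal dehydrogenase, fell by 0.90 ± 0.08. Of 5 tested endothelial and pericyte markers 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0449, adjusted p = 0.303 with an estimated correlation). The estimated correlations of the mesothelial and endothelial lists, −0.0107 and −0.123, also lay below the preset 0.01. Esam, a junctional adhesion molecule, rose by 1.19 ± 0.08, Pecam1 was at least 1.47-fold higher, and Plvap fell by 0.68 ± 0.10. The endothelial call was lost without parental 1 (camera adjusted p = 0.0526), parental 2 (0.06) or ID8-M 1 (0.0608), with cyclic loess (0.0715) and without a filter on dim probes (0.148).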

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

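The alternatives were fixed beforehand, except the removal of chromosome medians, which was chosen after the data were seen. The counts of changed probes, of changed genes and of shifted programme lists stayed within 1.5 times of 4610, 2748 and 4 under the settings run, apart from the estimated correlation, where camera called 0 programme lists and 0 cell type lists (3 and 1 at an unadjusted p under 0.05). The second list test, fry, passed many more lists than camera. Its adjusted p was over 0.05 only for alternative macrophage activation (0.762), fatty acid metabolism (0.225), growth factors (0.112) and oxidative phosphorylation (0.504). The mixed form of fry, which counts moves in either direction, gave an adjusted p of at most 6.86e-05 for each tested list. The 684 probes at 2-fold became 207 without background correction, 368 with the saddle-point background, 222 with the deposited normalized values and 312 with a detection p under 0.01 on all 6 arrays. Offsets and uncorrected background shrink log2 differences of dim probes by construction, and the stricter filter tests fewer probes. The 2 cell type lists became 1 with cyclic loess and without a filter, and 1 with the stricter filter, where too few endothelial genes remained. Leaving out each array in turn gave 3402 to 3844 probes, 678 to 704 at 2-fold, 2046 to 2295 genes, 3 to 4 programme lists and 1 to 2 cell type lists, with 1 without parental 1, parental 2 or ID8-M 1. With chromosome medians removed there were 3680 probes, 666 at 2-fold, 2166 genes (1956 shared with the 2748), 5 programme lists and 2 cell type lists. The share of rises among called genes was 50.1%, between 45.7% with the stricter filter and 58.4% with cyclic loess. With the replicate number as a block there were 3969 probes and 2330 genes. Deviations of same-numbered arrays correlated at 0.0374, −0.0933 and 0.0065, so the numbers are not taken to pair samples. Of 115 called genes named by the rule, 92 kept their call in every setting that gave them a value and none changed sign. The stricter filter left out others, so that 73 of the 115 had a value in each setting. Leaving out 1 array ended the call of 18 and the removal of chromosome medians that of 13. The interferon list was gained with median scaling (camera adjusted p = 0.0388) and the MHC class I list with chromosome medians removed (0.0286). The causes were not tested further. Signal over background limits dim probes, since mean background lay between 128.9 and 138.9 intensity units and the array medians between 138.7 and 148.2.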

Other observations

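All tests of explanations in this part were chosen only after the result was seen. The following genes were also chosen after their values were seen. Of 19 tested glutathione S-transferases 9 rose in ID8-M, 3 fell and 7 were not called. Besides Gstk1, Gstt3 was at least 9.94-fold higher (limma adjusted p = 1.81e-07) and undetected in parental ID8, Gstm1 rose by 1.22 ± 0.11 (SE, log2) and Mgst1 by 0.88 ± 0.10. Falls were seen for Gstp1, which fell by 0.26 ± 0.08 by its brightest probe, the only 1 of 3 that was called, and for the near-identical pair Gsta1 and Gsta2. Other large rises were those of Trf, transferrin, by 3.48 ± 0.08, of Rap1gap, which switches off a Ras-like GTPase, by 3.85 ± 0.11 (at least 3.84-fold and 1.67-fold by its other tested probes, at background in parental ID8), and of Smagp, a small adhesion glycoprotein, by 3.56 ± 0.11. Among other large falls, Loxl1, a collagen and elastin cross-linker, fell by 2.18 ± 0.08, Fscn1, the actin bundler fascin, fell by 2.29 ± 0.12, Grem1, an antagonist of BMP ligands, fell by 2.20 ± 0.14 and Inhba, a subunit of activin, fell by 1.92 ± 0.08.

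Genes of the same chromosome shifted together between the lines. Grouped by chromosome with the GRCm38.p6 annotation, 12 of 20 chromosomes passed the test, and 5 of these had a median log2 difference beyond 0.15 in either direction, at 0.36 for the one with Myc, −0.31 for the one with Junb, −0.29 for the one with Xist, −0.19 for the one with Jun and −0.19 for the one with Zeb1. Of the genes on the Myc chromosome 86.8% were higher in ID8-M, against 12.8% on the Junb chromosome. The 5 held 21.4% of tested genes and 32.8% of called genes. The test set each chromosome's median against 10000 gene sets matched on mean intensity. Each of the 5 exceeded the median of its sets by at least 0.163, with a permutation p of 1e-04, the smallest they can give. The 5 were chosen by passing this test, so that excess is no separate evidence against brightness-dependent normalization. Their matched sets had medians between −0.0275 and −0.0245, so mean intensity alone did not give shifts of this size. A shift confined to 1 part of a chromosome is argued against. On each of the 5 chromosomes all 4 equal parts in gene order lay on 1 side of 0. The smallest median of such a part was 66.9% of its chromosome's median. Lying on 1 side alone decides little, since all 4 parts did so on the chromosome with Sod1, which did not pass (permutation p = 0.718). A few small clusters would hardly move a median, so these medians do not test them. A difference in chromosome dosage between the lines is a candidate explanation for shifts along whole chromosomes, but no DNA was measured. Culture history and selection in the mouse were not tested as origins.

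There were more 2-fold rises than 2-fold falls, 516 against 168 probes. Background correction or scaling does not account for the excess, since rises made up at least 75.4% of these calls under 6 background and scaling settings. Probes near background in both lines as the whole cause are argued against, since rises made up 73.4% (95% interval 66.2% to 79.8%) of the 173 such probes whose mean over all 6 arrays lay above the median of tested probes. That binomial interval takes probes as independent, although some share a gene, and it does not measure the spread between samples. A probe at background in 1 line can still have such a mean. Removing chromosome-wide shifts left the share at 77%, and a detection p under 0.01 on all 6 arrays gave 68.6%, which decides nothing here because that filter leaves out probes detected in only 1 line. A difference between the cells themselves stays open and was not tested, and chip position cannot be told apart from the line.

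Of 5 tested endothelial genes 4 were higher in ID8-M and Plvap was lower, and of 2 tested macrophage genes Mpeg1 was higher and Cd14 lower. RNA from endothelial cells is argued against, since 0 of the 5 abundant transcripts Cdh5, Cldn5, Vwf, Emcn and Tie1 were detected on any ID8-M array. RNA from macrophages is argued against likewise, with 0 of the 8 transcripts Lyz2, C1qa, C1qb, C1qc, Tyrobp, Fcer1g, Laptm5 and Csf1r detected there. Esam had a mean log2 intensity of 10.62 on the parental arrays, so the parental line already held its RNA. Mpeg1 was also detected on all 3 parental arrays, though at a mean of only 5.84, and Pecam1 on none. That the cancer cells themselves account for the rises of Esam, Pecam1, Flt1, Eng and Mpeg1 is a hypothesis that these arrays leave open.

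Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. For limma's calls, 1 of the 10 splits, the real one, gave as many as 4610 probes, 684 at 2-fold and 2748 genes. The highest of the other splits gave 0 in each case. Each other split puts arrays of both lines in each group, so the line difference enters the spread within groups. Low limma counts there follow from the design and are no separate support. For camera's calls, 1 of the 10 gave as many as 4 programme lists, with 3 the highest of the others, and 1 of the 10 gave as many as 2 cell type lists, with 0 the highest of the others.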
